A study of Mus musculus with 12 samples.

How the data were processed

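RNA of whole mouse embryos was profiled on 12 Clariom S Mouse arrays. Females were superovulated and mated naturally, and the day of the vaginal plug counted as E0.5. Per the labels, pronuclear embryos were washed in KSOM, an embryo culture medium, and incubated, 2-cell embryos and morulae were collected 1 and 2 days after the plug, and E10.5 and E16.5 embryos were taken from the mother. RNA was extracted with QIAzol, and biotinylated targets were made from 2 ng of total RNA with a kit for small inputs. The early stages were pooled, with an unstated number of embryos per pool.

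The authors deposited gene-level signals on the log2 scale, made by signal space transformation and robust multi-array averaging (SST-RMA). The submitters' processing notes name the Transcriptome Analysis Console, without a version, and per the file headers the annotation is release na36 on mm10. The array files' column names carry the SST-RMA label. The same deposited table holds the authors' F test over the stages (p-value and false discovery rate, of a variance model that is not given in the sources used here) and, in another column per stage, a flag of T or F (other), whose detection rule is likewise not given and which decided no call here. A second deposited table holds the same log2 values, with 0 probe sets that differ, so no fit of the other table was made. Array medians ranged from 6.19 to 6.59, and for arrays no counting depth applies.

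Of 22206 probe sets, 21367 carried exactly 1 gene symbol, 836 several and 3 none. Only those with 1 symbol were used, and of several for a gene the brightest over all arrays was kept (211 left out), which left 21156 genes. Many probe sets with several symbols pair a host gene with a small RNA in its intron, which left out genes such as H19, Xist, the adult globins and some ribosomal protein genes. Positions are those of the deposited annotation on mm10, counted from 1, and span the annotated transcript. RefSeq accessions of 19758 genes were found in a RefSeq gene table of assembly GRCm38.p6, 18935 with the same symbol. The symbols of the files were kept.

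Stages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) in 1 model of the 5 stages on all 12 arrays, because 2 or 3 arrays per stage are too few to estimate a spread alone. The 4 contrasts of consecutive stages were tested two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and an F test asked which genes differ between any stages. Genes higher at the 2-cell stage than at both neighbours were those that passed upward and then downward. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The comparisons, lists, rule for named genes and alternative settings, apart from those stated below as added, were fixed before the data were examined.

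The 33 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. They were: maternal oocyte transcripts, 2-cell activation genes, heat shock and immediate early genes, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, proteasome, cell cycle, DNA methylation and chromatin regulators, pluripotency, trophectoderm and epithelium of the morula, primitive endoderm, Hox genes, somite and limb bud patterning, neural progenitors, neurons, glia and Schwann cells, erythroid cells, leukocytes, heart muscle, skeletal muscle, cartilage and bone, epidermis, liver, lung, gut, pancreas and kidney in 1 list, endothelium, imprinted genes, and interferon and antigen presentation. Markers of cells that could be carried along (cumulus and granulosa cells, sperm, placenta and decidua) and sex chromosome markers completed them. A call with an adjusted p above 0.05 under an estimated correlation is given beside the list.

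Genes were named by rule. Per comparison these were the 5 largest rises and 5 largest falls past the threshold whose arrays did not overlap between the stages, leaving out provisional names and chemosensory receptors. From each list assigned to the comparison came the 3 members with the largest change in its main direction and the 1 with the largest opposite change, and from the lists of other cells and of sex at most 2 members. Of the genes that this rule names, 2 are not reported here. Changes are given with the standard error of the fit, and signals as mean and standard deviation.

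The alternative settings were an intensity trend with a robust prior, array weights per stage, the replicate number as a block, quantile normalization applied again, cyclic loess, arrays centred on the receptor median or the upper quartile, a filter on dim genes (15660 kept, 5496 removed), the mean of all probe sets of a gene, every probe set by itself, a stricter threshold of 0.01, a minimum 2-fold change, fits of only the 2 stages compared, and leaving out each array. Added after seeing the data were host gene probe sets with several symbols, because of the ribosomal protein genes, and fits of 1 date only. The column names carry 2 dates, which were not used as a term because each stage lies within 1 date.

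The test was checked on simulated data of 21156 genes, 200 of them changed. A change of 2 log2 units was recovered for 90.9% of genes in 2-cell versus pronuclear, 81.8% in morula versus 2-cell, 97.0% in E10.5 versus morula and 97.0% in E16.5 versus E10.5. At 1 log2 unit the shares were 10.4%, 7.46%, 17.9% and 25.4%, and at 0.5 log2 units 0%, 1.49%, 0% and 0%. With so few changed genes, small changes mostly went unseen. In the real comparisons 35.6% to 51.9% of genes passed, and the adjusted threshold is less strict where a larger share changes. The recovered shares therefore do not carry over to the real comparisons.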

Results

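Gene expression was measured on Clariom S Mouse arrays, which carry probes for the exons of well-annotated genes, in whole mouse embryos of 5 stages. Pools of embryos were used at the pronuclear stage (E0.5, 2 arrays), the 2-cell stage (E1.5, 2 arrays) and the morula stage (E2.5, 2 arrays). At E10.5 and at E16.5, 3 arrays each held RNA of 1 embryo per array. The comparisons ask which transcripts rise or fall from each stage to the next. RNA came from whole embryos, so a rise or fall can reflect the share of a tissue as well as expression within its cells. The share of a tissue and expression within cells were not told apart. Signals of 21156 genes were compared on the log2 scale on which they were deposited, and array medians lay between 6.19 and 6.59. All changes below are in log2 units. Signals reached 19.53, so these units are not calibrated as folds of RNA abundance. The number of arrays limits the precision of every value.

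Arrays of a stage lay close together: correlations across genes, which are not independent replicates, ran from 0.978 to 0.992 within a stage and from 0.654 to 0.888 between stages. The first 3 principal components held 55.0%, 18.9% and 13.5% of the variance. Olfactory and vomeronasal receptor genes (1404 measured) served as a measure of background. Their 95th percentile lay at 5.97 in pronuclear embryos, 6.50 in 2-cell embryos, 6.17 in morulae, 5.48 at E10.5 and 5.35 at E16.5. Of these receptors, 18 rose by over 2 log2 units to the 2-cell stage and 14 of them fell again, so the range is not background alone there. Without them its 2-cell value was 6.40. Where the lower of 2 stages lay within this receptor range and the higher well above it, the change is a lower bound. Changes between 2 stages within the range can follow the background and are not lower bounds. Whether pools or embryos came from separate mothers is not given in the labels, so p-values measure the spread between these samples only. The fit shares 1 spread over pools and single embryos, so p-values of the early comparisons also rest on the spread between late embryos.

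Most genes differed between stages. In limma's F test over the 5 stages, 16696 genes (78.9%) passed an adjusted p of 0.05, and the authors' deposited table listed 16685 of the tested genes at a false discovery rate below 0.05, all of which also passed here. Between consecutive stages, 1477 genes changed in all 4 comparisons and 4865 in none of them.

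**Figure D1:**
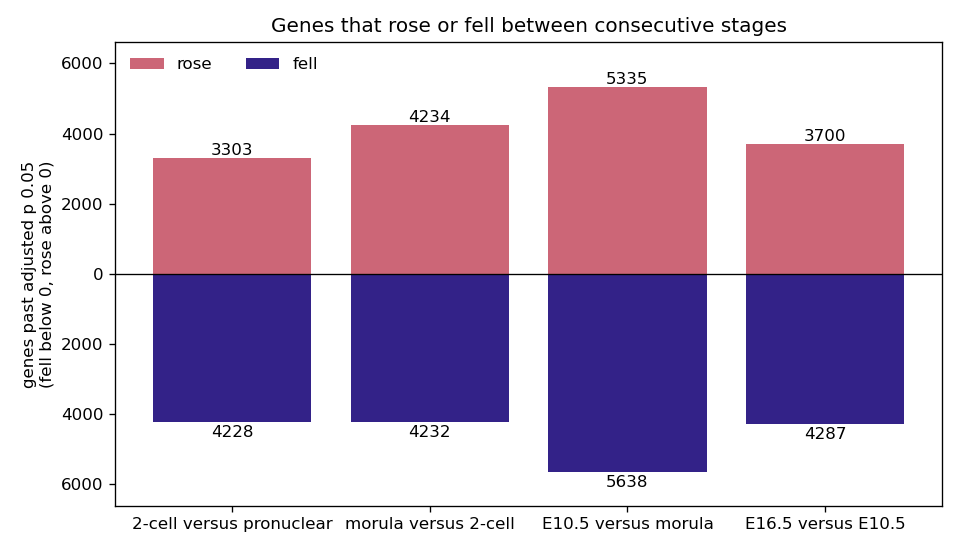
Number of genes past an adjusted p of 0.05 (vertical axis) in each comparison of consecutive stages (horizontal axis), with genes that rose above 0 and genes that fell below 0. The step from the morula to E10.5 held the most, 5335 that rose and 5638 that fell.

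From the pronuclear to the 2-cell stage, transcripts known from the first wave of embryonic transcription rose and many transcripts stored in the oocyte fell. The mean signal of the 2-cell activation genes rose from 6.99 ± 0.068 to 12.55 ± 0.018 (SD, n = 2 each), and 38 of 42 of them passed the test upward. The mean of the maternal oocyte transcripts went from 14.78 ± 0.032 to 12.67 ± 0.036 (SD, n = 2 each), with 35 of 52 that fell. Guca1a, known as an activator of guanylate cyclase in photoreceptors, had the largest rise, to 16.49 (n = 2). Transcripts of 55 of 62 cytosolic ribosomal proteins also rose.

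Here and at the later steps, rankings of rises and falls leave out provisional names and chemosensory receptors. The 5 largest rises were those of Guca1a (chromosome 17, 47394558 to 47400584), Tdpoz3 (chromosome 3, 93826020 to 93827117), Tdpoz2 (chromosome 3, 93651542 to 93652686), Timd2 (chromosome 11, 46668960 to 46707104) and Ubtfl1 (chromosome 9, 18404418 to 18411502). Guca1a rose by 11.99 ± 0.28 (SE, adjusted p = 1.08e-12), and the other 4 by 9.43 to 10.18 (adjusted p at most 9.54e-11). Tdpoz2 and Tdpoz3 encode related proteins with TRAF-like and POZ domains, and Timd2 an immunoglobulin and mucin domain protein. Whether probes tell Tdpoz2, Tdpoz3 and Gm2022, named below, from genes of similar sequence was not tested here. The same holds for the other Tdpoz, Zscan4, Usp17l, Obox and Gm-named members of the 2-cell activation genes. Counts of that list may therefore not be counts of separately measured genes. All 5 started within the receptor range, so these rises are lower bounds. Among the largest falls, Oas1h (chromosome 5, 120861421 to 120873512), of the oligoadenylate synthetase family, went from 14.77 ± 0.091 to 7.83 ± 1.31 (SD, n = 2 each), and fell by 6.94 ± 0.49 (SE, adjusted p = 3.83e-08). Mos (chromosome 4, 3870657 to 3872105), the kinase that keeps the oocyte in meiotic arrest, fell by 6.17 ± 0.32 (SE, adjusted p = 1.56e-09). Cldn8 (chromosome 16, 88560826 to 88563183), a tight junction claudin, fell by 5.91 ± 0.44 (SE, adjusted p = 6.67e-08). The tetraspanin gene Tspan33 (chromosome 6, 29694222 to 29718559) fell by 5.90 ± 0.35 (SE, adjusted p = 7.09e-09). Rgs2 (chromosome 1, 143999338 to 144004161), a regulator of G protein signalling, fell by 5.86 ± 0.34 (SE, adjusted p = 5.73e-09) and stayed well expressed at 11.58. Mos and Tspan33 ended within the receptor range.

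Among the maternal oocyte transcripts, 4 of 52 measured genes rose, 35 fell and 13 did not pass (5 and 37 adjusted over the list alone), with camera adjusted p = 1.51e-11. Tle6, a component of the subcortical maternal complex, fell by 5.35 ± 0.32 (SE), and Zar1, a maternal effect gene, fell by 5.35 ± 0.33 (SE), each with an adjusted p of 1.01e-08 or less. Omt2b went the other way and rose by 1.58 ± 0.44 (SE), a call that was lost without pronuclear replicate 1 (adjusted p = 0.0521, range over the alternatives 0.00389 to 0.0521). Of the 2-cell activation genes, 38 of 42 measured genes rose, 2 fell and 2 did not pass (38 and 3 adjusted over the list alone), with camera adjusted p = 5.51e-30. Gm2022 rose by 9.96 ± 0.43 (SE, adjusted p = 3.14e-10) besides Tdpoz2 and Tdpoz3, while Arg2, the mitochondrial arginase, fell by 3.16 ± 0.27 (SE, adjusted p = 3.17e-07).

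Transcripts of the translation machinery rose. In ribosome biogenesis 21 of 41 measured genes rose, 6 fell and 14 did not pass (24 and 6 adjusted over the list alone), with camera adjusted p = 4.20e-05. Nop16 rose by 6.79 ± 0.30, Nop2, a methyltransferase of ribosomal RNA, rose by 5.58 ± 0.30, and Nhp2, a protein of small nucleolar particles, rose by 4.88 ± 0.28 (SE, adjusted p at most 4.39e-09), and Noc4l fell by 4.66 ± 0.31 (SE, adjusted p = 1.96e-08). For cytosolic ribosomal proteins 55 of 62 measured genes rose, 0 fell and 7 did not pass (57 and 0 adjusted over the list alone), with camera adjusted p = 1.98e-23, adjusted p = 0.108 with an estimated correlation. Pluripotency genes were the fifth list to pass: 10 of 25 measured genes rose, 3 fell and 12 did not pass (10 and 3 adjusted over the list alone), with camera adjusted p = 0.00949, adjusted p = 0.162 with an estimated correlation.

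Several lists held genes that moved in opposite directions and did not pass as a list. Of the heat shock and immediate early genes, 2 of 15 measured genes rose, 6 fell and 7 did not pass (2 and 7 adjusted over the list alone), with camera adjusted p = 0.545: Dnajb1, a co-chaperone, fell by 3.25 ± 0.28, the phosphatase gene Dusp1 fell by 2.28 ± 0.34, and the chaperone gene Hsp90aa1 fell by 1.71 ± 0.27 (SE), whereas Hspb1, a small heat shock protein, rose by 4.19 ± 0.36 (SE, adjusted p = 2.94e-07). In the proteasome 7 of 30 measured genes rose, 13 fell and 10 did not pass (8 and 13 adjusted over the list alone), with camera adjusted p = 0.548. Psma7 fell by 3.19 ± 0.31, Psmc2 fell by 2.43 ± 0.26, Psmc5 fell by 1.94 ± 0.37 and Psmb1 rose by 2.65 ± 0.29 (SE, adjusted p at most 6.63e-04). Among cell cycle genes, 9 of 44 measured genes rose, 12 fell and 23 did not pass (9 and 12 adjusted over the list alone), with camera adjusted p = 0.885. Ccne1, which encodes cyclin E1, rose by 6.80 ± 0.27 (SE, adjusted p = 1.57e-10), while the replication factor gene Gins1 fell by 3.60 ± 0.30, the spindle checkpoint gene Bub1b fell by 3.39 ± 0.37 and the phosphatase gene Cdc25a fell by 3.13 ± 0.33 (SE). Among DNA methylation and chromatin regulators, 10 of 35 measured genes rose, 13 fell and 12 did not pass (10 and 14 adjusted over the list alone), with camera adjusted p = 0.842. Uhrf1, which recruits the maintenance methyltransferase, fell by 4.05 ± 0.35, Zfp57, which protects imprints, fell by 2.85 ± 0.37, and the histone methyltransferase gene Setdb1 fell by 2.67 ± 0.28 (SE), while the deacetylase gene Hdac1 rose by 5.12 ± 0.28 (SE, adjusted p = 2.75e-09).

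Markers of other cells did not pass as lists. Of the cumulus and granulosa cell markers 2 of 21 measured genes rose, 6 fell and 13 did not pass (2 and 7 adjusted over the list alone), with camera adjusted p = 0.372. Inha, an inhibin subunit, fell by 3.65 ± 0.33 and the prostaglandin synthase gene Ptgs2 fell by 2.63 ± 0.38 (SE, adjusted p at most 5.58e-05). Of the sperm markers 1 of 12 measured genes rose, 2 fell and 9 did not pass (1 and 2 adjusted over the list alone), with camera adjusted p = 0.829. The protamine gene Prm2 fell by 1.80 ± 0.51 (SE, adjusted p = 0.0113), a call lost without pronuclear replicate 2 (adjusted p = 0.167), without 2-cell replicate 1 (0.0769) and in a fit of the early arrays alone (0.0689, range over the alternatives 0.00204 to 0.167). Pgk2 rose by 1.30 ± 0.32 (SE, adjusted p = 0.00459), which was lost without 2-cell replicate 2 (adjusted p = 0.0518, range 0.00243 to 0.0518), with both stages within the receptor range. Of the placenta and decidua markers 3 of 21 measured genes rose, 2 fell and 16 did not pass (3 and 1 adjusted over the list alone), with camera adjusted p = 0.855. Syna, a syncytin gene, rose by 2.80 ± 0.32 (SE, adjusted p = 5.11e-06) from within the receptor range, and Tpbpb differed by 1.50 ± 0.59 (SE, adjusted p = 0.0622; 0.00302 without 2-cell replicate 1, range 0.00302 to 0.600). None of the 4 measured sex chromosome markers passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.653). Uty, on the Y chromosome, lay at 3.54 and 7.84 (adjusted p = 0.134), but passed in a fit of the early arrays alone (3.88e-05) and without E10.5 replicate 3 (0.0263, range 3.88e-05 to 0.335). It also passed in a fit of these 2 stages only (2.55e-04) and with the replicate number as a block (0.0299). For Kdm5d the values were 3.12 and 5.63 (adjusted p = 0.310; 0.00362 in the early arrays alone, range 0.00362 to 0.591).

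In all, 7531 of 21156 genes changed between the pronuclear and the 2-cell stage, 3303 upward and 4228 downward. Changes of over 5 log2 units comprised 190 rises and 37 falls. In oxidative phosphorylation 23 of 74 measured genes rose, 15 fell and 36 did not pass (25 and 16 adjusted over the list alone), with camera adjusted p = 0.173, and 0.0352 after quantile normalization (range 0.0352 to 0.445). Of the 33 lists 5 passed, and 3 of them (maternal oocyte transcripts, 2-cell activation genes and ribosome biogenesis) also passed with an estimated correlation. A fit of the 6 arrays of the early date alone called 6356 genes, 6294 of them shared. The division between rises and falls depended on scaling, with 3843 up and 3606 down centred on the upper quartile and 2531 up and 4623 down centred on the receptors.

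From the 2-cell stage to the morula, genes of the trophectoderm and epithelium list and all measured proteasome genes rose, and the oocyte and 2-cell transcripts fell. Fbp2, a fructose bisphosphatase, rose from 4.91 ± 0.73 to 15.47 ± 0.23 (SD, n = 2 each), and Cldn4, a claudin of tight junctions, rose from 5.01 ± 0.76 to 14.14 ± 0.22 (SD, n = 2 each). The 30 proteasome genes rose by a median of 2.63. Tcl1, a coactivator of Akt kinase that is abundant in oocytes, fell from 18.82 ± 0.032 to 5.93 ± 0.24 (SD, n = 2 each). Of the maternal oocyte transcripts 47 of 52 fell, and of the 2-cell activation genes 37 of 42.

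Among the largest rises were those of Fbp2 (chromosome 13, 62836877 to 62858400), the fatty acid binding protein gene Fabp3 (chromosome 4, 130308595 to 130315463), Cldn4 (chromosome 5, 134945123 to 134946934) and the pantetheinase gene Vnn1 (chromosome 10, 23894688 to 23905343). Fbp2 rose by 10.56 ± 0.42 (SE, adjusted p = 7.70e-11), Fabp3 by 9.43 ± 0.42, Cldn4 by 9.13 ± 0.45 and Vnn1 by 9.09 ± 0.38 (SE, adjusted p at most 5.96e-10), each from within the receptor range and so at least by that amount. The 5 largest falls all lay in the Tcl1 cluster on chromosome 12: Tcl1 (105216750 to 105222793) fell by 12.89 ± 0.34 (SE, adjusted p = 3.16e-12), Tcl1b1 fell by 12.79 ± 0.30, Tcl1b2 fell by 12.36 ± 0.36, Tcl1b4 fell by 11.65 ± 0.39 and Tcl1b3 fell by 11.47 ± 0.38 (SE, adjusted p at most 1.08e-11), all into the receptor range. The Tcl1b genes are close relatives in sequence, and whether their probes tell them apart was not tested here.

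Of the maternal oocyte transcripts 2 of 52 measured genes rose, 47 fell and 3 did not pass (2 and 48 adjusted over the list alone), with camera adjusted p = 4.74e-31. Khdc3, of the subcortical maternal complex, was the larger of the 2 that rose, by 4.76 ± 0.31 (SE, adjusted p = 9.84e-09). Among 2-cell activation genes 1 of 42 measured genes rose, 37 fell and 4 did not pass (2 and 38 adjusted over the list alone), with camera adjusted p = 2.87e-22. The oocyte-type homeobox genes Obox5 and Obox3 fell by 10.38 ± 0.31 and 8.30 ± 0.34, the zinc finger gene Zfp352 fell by 6.55 ± 0.49 (SE, adjusted p at most 4.89e-08), and Pramel7 rose by 2.28 ± 0.43 (SE, adjusted p = 5.19e-04).

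Lists of protein synthesis, protein breakdown and respiration rose. For cytosolic ribosomal proteins 52 of 62 measured genes rose, 0 fell and 10 did not pass (55 and 0 adjusted over the list alone), with camera adjusted p = 2.89e-16, adjusted p = 0.187 with an estimated correlation. Rpl3 rose by 3.77 ± 0.30, Rpl35a rose by 3.27 ± 0.36 and Rpl5 rose by 3.19 ± 0.28 (SE, adjusted p at most 2.53e-06). In ribosome biogenesis 22 of 41 measured genes rose, 6 fell and 13 did not pass (23 and 6 adjusted over the list alone), with camera adjusted p = 0.00398, adjusted p = 0.0738 with an estimated correlation. For oxidative phosphorylation 60 of 74 measured genes rose, 1 fell and 13 did not pass (64 and 1 adjusted over the list alone), with camera adjusted p = 1.66e-16, adjusted p = 0.0884 with an estimated correlation. The subunit genes of complex I Ndufs7, Ndufb7 and Ndufa5 rose by 4.77 ± 0.30, 4.36 ± 0.28 and 4.04 ± 0.26 (SE). Cox8a, of cytochrome c oxidase, fell by 1.05 ± 0.31 (SE, adjusted p = 0.0125), which was lost without 2-cell replicate 2 (adjusted p = 0.108), without morula replicate 1 (0.0690) and in a fit of these 2 stages alone (0.0572, range over the alternatives 5.61e-04 to 0.108). In the proteasome 30 of 30 measured genes rose, 0 fell and 0 did not pass (30 and 0 adjusted over the list alone), with camera adjusted p = 2.71e-16. Glycolysis did not pass: 6 of 20 measured genes rose, 5 fell and 9 did not pass (7 and 5 adjusted over the list alone), with camera adjusted p = 0.999.

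Pluripotency genes rose in part: 15 of 25 measured genes rose, 3 fell and 7 did not pass (16 and 3 adjusted over the list alone), with camera adjusted p = 0.00189, adjusted p = 0.103 with an estimated correlation. Nanog rose by 8.22 ± 0.41 (SE, adjusted p = 5.70e-10), the Nodal coreceptor gene Tdgf1 rose by 5.67 ± 0.31 and the transcription factor gene Tfcp2l1 rose by 4.81 ± 0.32 (SE), all from within the receptor range, while Tcl1, also held in this list, fell. In the list of trophectoderm and epithelium of the morula 27 of 34 measured genes rose, 1 fell and 6 did not pass (27 and 1 adjusted over the list alone), with camera adjusted p = 5.81e-10. Besides Cldn4, the claudin gene Cldn7 rose by 8.88 ± 0.36 and the aquaglyceroporin gene Aqp3 rose by 7.58 ± 0.31 (SE, adjusted p at most 9.98e-11), and Slc9a3r1, a scaffold protein of microvilli, fell by 1.29 ± 0.27 (SE, adjusted p = 0.00133). Primitive endoderm genes went both ways, so that 5 of 19 measured genes rose, 4 fell and 10 did not pass (5 and 4 adjusted over the list alone), with camera adjusted p = 0.778. The endocytic receptor gene Cubn rose by 4.22 ± 0.49, the transcription factor gene Gata6 rose by 2.66 ± 0.40 and the laminin gene Lamc1 rose by 1.82 ± 0.32 (SE), against the proteoglycan gene Srgn, which fell by 6.17 ± 0.28 (SE, adjusted p = 2.20e-10).

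Cumulus and granulosa cell markers fell as a list between these stages: 2 of 21 measured genes rose, 7 fell and 12 did not pass (2 and 7 adjusted over the list alone), with camera adjusted p = 0.0127, adjusted p = 0.0738 with an estimated correlation. Cyp11a1, the side-chain cleavage enzyme of steroid synthesis, went from 15.36 ± 0.13 to 8.11 ± 0.78 (SD, n = 2 each) and Tnfaip6, of the cumulus matrix, fell by 4.89 ± 0.33 (SE, adjusted p = 1.55e-08). These falls accompany those of the maternal and 2-cell lists above. Among sperm markers, 0 of 12 measured genes rose, 3 fell and 9 did not pass (0 and 3 adjusted over the list alone), with camera adjusted p = 0.842. Prm2 fell by 2.08 ± 0.51 (SE, adjusted p = 0.00376; 0.0763 without morula replicate 1, range 1.99e-04 to 0.0763) and Ldhc fell by 1.68 ± 0.47 (SE, adjusted p = 0.00862; 0.131 without 2-cell replicate 1 and 0.0501 without morula replicate 2, range 0.00171 to 0.131). Among placenta and decidua markers, 3 of 21 measured genes rose, 4 fell and 14 did not pass (3 and 4 adjusted over the list alone), with camera adjusted p = 0.877, and the prolactin family gene Prl8a2 fell by 6.59 ± 0.29 and the pregnancy-specific glycoprotein gene Psg17 fell by 3.86 ± 0.30 (SE). No sex chromosome marker of 4 passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.885). Ddx3y lay at 6.13 and 9.35 (adjusted p = 0.165; 0.00161 in the early arrays alone, range 0.00161 to 0.396), and Uty at 7.84 and 6.55 (adjusted p = 0.665; 0.0108 in the early arrays alone, range 0.0108 to 0.800). In a fit of these 2 stages only, both passed (0.00380 and 0.0249), and Ddx3y also passed with the replicate number as a block (0.0394).

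Between the 2-cell stage and the morula 8466 genes changed, 4234 upward and 4232 downward, and 88 rose and 327 fell by more than 5 log2 units. Of the 33 lists 9 passed, 6 upward and 3 downward. With an estimated correlation 4 did: maternal oocyte transcripts, 2-cell activation genes, proteasome, and trophectoderm and epithelium. Obox3, Gata6, Cldn7, Aqp3, Tnfaip6, Prm2, Ldhc, Prl8a2 and Psg17 lay within the receptor range at their lower stage. The early arrays alone gave 7367 changed genes, 7301 of them shared. Scaling moved the division of rises and falls, to 5434 up and 3572 down centred on the upper quartile and 3629 up and 4258 down centred on the receptors.

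Both early comparisons share the 2-cell arrays, and 1293 genes were higher at the 2-cell stage than at both neighbouring stages. They included 34 of the 42 measured 2-cell activation genes and 3 of 52 maternal oocyte transcripts, and 54 genes rose and then fell by over 5 log2 units each. Among the 54 are Zscan4, Usp17l and Gm-named genes, which the probes may not tell from their relatives. If rises and falls were independent of each other, 661 such genes would result. The opposite pattern, a fall and then a rise, held 1183 genes (846 if independent). Genes that rose at both steps numbered 701 (661 if independent), and genes that fell at both steps 1211 (846 if independent). Every pattern thus lay above its independent number, and an excess is not particular to the 2-cell peak, though it was largest there. Because the 2 comparisons use the same 2-cell arrays, error in these arrays moves the counts of the peak and of its opposite in the same direction. In a fit of the early arrays alone the 2-cell peak held 1059 genes.

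**Figure D2:**
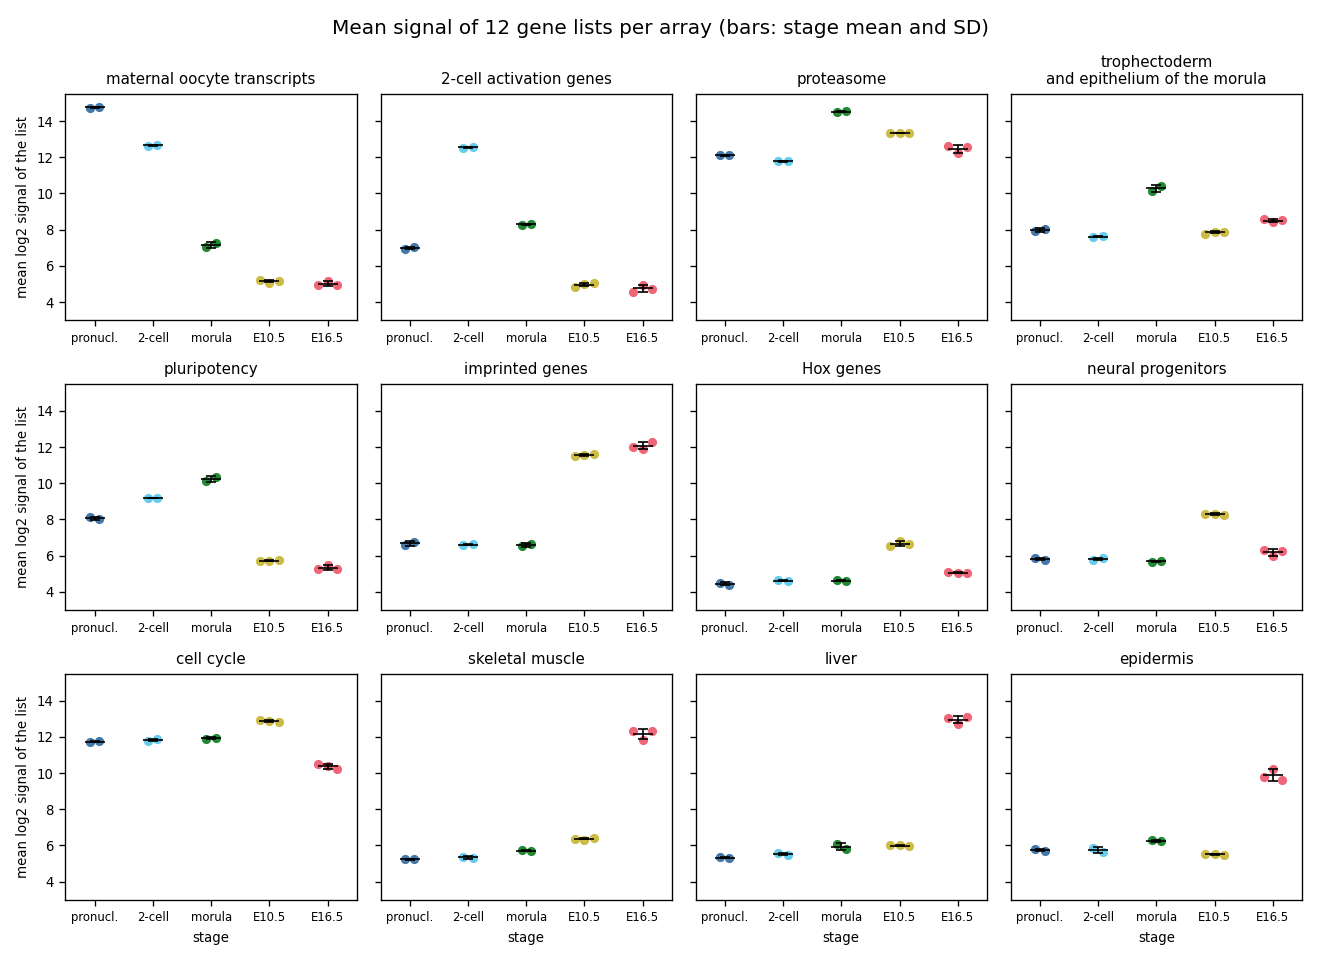
Mean log2 signal of the members of 12 gene lists (vertical axes) on each array (points) at the 5 stages (horizontal axes, pronucl. for pronuclear), with bars for the stage mean and SD (n = 2 or 3 arrays). The mean of the 2-cell activation genes is highest at the 2-cell stage (12.55), that of the proteasome at the morula stage (14.53) and that of liver genes at E16.5 (12.96).

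From the morula to E10.5, when the embryo has formed its organ rudiments and circulation, embryonic globins, imprinted genes and patterning genes rose, and pluripotency genes fell. Hbb-y, the embryonic beta-like globin of primitive red cells, rose from 4.26 ± 0.17 to 19.41 ± 0.051 (SD, n = 2 and 3). Imprinted genes rose in 22 of 26, and their mean signal went from 6.59 ± 0.11 (SD, n = 2) to 11.57 ± 0.047 (SD, n = 3). Pou5f1, a core pluripotency factor, fell from 16.43 ± 0.033 to 3.59 ± 0.53 (SD, n = 2 and 3), and 23 of 25 pluripotency genes fell. Of the Hox genes 24 of 34 rose.

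The largest rises were those of Hbb-y (chromosome 7, 103851745 to 103853240), Hba-x (chromosome 11, 32276400 to 32278116), Hbb-bh1 (chromosome 7, 103841636 to 103843164), Mest (chromosome 6, 30723547 to 30748466) and Tmsb4x (chromosome X, 167207093 to 167209315). Hbb-y rose by 15.15 ± 0.30, Hba-x rose by 14.44 ± 0.30 and Hbb-bh1 rose by 13.65 ± 0.31 (SE, adjusted p at most 1.15e-13), all embryonic globins. Mest, an imprinted gene expressed from the paternal allele, rose by 12.93 ± 0.42 (SE, adjusted p = 3.92e-12), from 6.50 ± 1.49 to 19.43 ± 0.059 (SD, n = 2 and 3). Tmsb4x, the actin-binding thymosin, rose by 12.77 ± 0.36 (SE, adjusted p = 7.80e-13). Except for Mest, these genes started within the receptor range. Mest and Hbb-y reached the top of the scale at E10.5, where array maxima lay between 19.41 and 19.48, so a ceiling of the signal was not excluded and the sizes of these rises and their order are not exact. The largest falls were those of Dppa3 (chromosome 6, 122626410 to 122630272), Fbxo15 (chromosome 18, 84935025 to 84981392), Dppa5a (chromosome 9, 78367052 to 78368199), Timd2 (chromosome 11, 46668960 to 46707104) and Pou5f1 (chromosome 17, 35506018 to 35510777). Dppa3 fell by 13.62 ± 0.28, Fbxo15 fell by 13.19 ± 0.31, Dppa5a fell by 13.05 ± 0.30, Timd2 fell by 13.04 ± 0.30 and Pou5f1 fell by 12.84 ± 0.30 (SE, adjusted p at most 1.29e-13) into the receptor range. Dppa3, Fbxo15 and Dppa5a are known from oocytes, early embryos and pluripotent cells.

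Genes of the early embryo fell as lists. For pluripotency 1 of 25 measured genes rose, 23 fell and 1 did not pass (1 and 23 adjusted over the list alone), with camera adjusted p = 6.32e-11. Dppa2 fell by 9.79 ± 0.36 (SE, adjusted p = 1.06e-11), whereas Sox2, which is also a gene of neural progenitors, rose by 3.68 ± 0.41 (SE, adjusted p = 1.69e-06). In the list of trophectoderm and epithelium of the morula 5 of 34 measured genes rose, 20 fell and 9 did not pass (5 and 20 adjusted over the list alone), with camera adjusted p = 2.07e-04, adjusted p = 0.0738 with an estimated correlation. The water channel genes Aqp9 and Aqp3 fell by 10.85 ± 0.27 and 7.42 ± 0.28, and Cldn7 fell by 9.85 ± 0.33 (SE, adjusted p at most 1.50e-11), while Id2, an inhibitor of basic helix-loop-helix factors, rose by 4.35 ± 0.31 (SE, adjusted p = 1.33e-08). Among maternal oocyte transcripts, 4 of 52 measured genes rose, 39 fell and 9 did not pass (4 and 41 adjusted over the list alone), with camera adjusted p = 6.21e-08. For 2-cell activation genes 2 of 42 measured genes rose, 35 fell and 5 did not pass (4 and 36 adjusted over the list alone), with camera adjusted p = 3.84e-12.

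Lists of patterning, neural and heart genes rose. Of the Hox genes 24 of 34 measured genes rose, 1 fell and 9 did not pass (26 and 1 adjusted over the list alone), with camera adjusted p = 3.95e-08. Hoxd11, Hoxb9 and Hoxa2 rose by 5.00 ± 0.38, 4.77 ± 0.27 and 4.66 ± 0.28 (SE, adjusted p at most 2.85e-08). Hoxb13 fell by 1.07 ± 0.28 (SE, adjusted p = 0.00503) with both stages within the receptor range, so that this is no lower bound, and its call was lost without morula replicate 1 (adjusted p = 0.115), with cyclic loess (0.0783) and after centring on the receptors (0.143, range 0.00102 to 0.143). In somite and limb bud patterning 22 of 36 measured genes rose, 0 fell and 14 did not pass (22 and 0 adjusted over the list alone), with camera adjusted p = 8.77e-07. Prrx1 and Prrx2, homeobox genes of limb and face mesenchyme, rose by 8.18 ± 0.40 and 5.15 ± 0.33, and the Notch ligand gene Dll1 rose by 5.15 ± 0.39 (SE). Among neural progenitor genes, 17 of 21 measured genes rose, 0 fell and 4 did not pass (17 and 1 adjusted over the list alone), with camera adjusted p = 1.90e-06: Fabp7, a radial glia marker, rose by 8.19 ± 0.38, the RNA-binding protein gene Msi1 rose by 6.68 ± 0.50 and the spinal cord homeobox gene Dbx1 rose by 4.56 ± 0.32 (SE). For neurons 19 of 33 measured genes rose, 1 fell and 13 did not pass (19 and 1 adjusted over the list alone), with camera adjusted p = 4.96e-06, adjusted p = 0.215 with an estimated correlation. Among heart muscle genes, 14 of 22 measured genes rose, 2 fell and 6 did not pass (15 and 2 adjusted over the list alone), with camera adjusted p = 3.00e-04. Nppa, the atrial natriuretic peptide gene, rose by 6.57 ± 0.46, the myosin light chain gene Myl2 rose by 6.40 ± 0.42 and the troponin gene Tnnt2 rose by 4.67 ± 0.29 (SE, adjusted p at most 9.42e-09), and Nppb fell by 3.16 ± 0.33 (SE, adjusted p = 8.56e-07).

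Of the erythroid genes 15 of 24 measured genes rose, 0 fell and 9 did not pass (16 and 1 adjusted over the list alone), with camera adjusted p = 4.35e-06, adjusted p = 0.0729 with an estimated correlation, led by the embryonic globins. For endothelium 13 of 19 measured genes rose, 0 fell and 6 did not pass (13 and 0 adjusted over the list alone), with camera adjusted p = 6.02e-05, adjusted p = 0.174 with an estimated correlation. Among imprinted genes, 22 of 26 measured genes rose, 2 fell and 2 did not pass (22 and 2 adjusted over the list alone), with camera adjusted p = 3.97e-12. The paternally expressed zinc finger gene Peg3 rose by 10.75 ± 0.32 and the adaptor gene Grb10 rose by 10.34 ± 0.41 (SE, adjusted p at most 2.14e-11), while Phlda2, a growth-limiting gene of the placenta, fell by 2.05 ± 0.29 (SE, adjusted p = 2.06e-05). Primitive endoderm genes passed narrowly, since 8 of 19 measured genes rose, 3 fell and 8 did not pass (8 and 3 adjusted over the list alone), with camera adjusted p = 0.0498, adjusted p = 0.236 with an estimated correlation. That call held in 8 of 22 alternatives (range 0.0231 to 0.223). Quantile normalization applied again, cyclic loess and centring on the receptors or the upper quartile ended it (0.0595 to 0.0775). The replicate number as a block (0.0579) and a filter on dim genes (0.223) did so too. It was also lost without E10.5 replicate 1 (0.0510), E10.5 replicate 2 (0.0749) or E16.5 replicate 3 (0.0520). Leaving out morula replicate 1 or any array of the pronuclear or 2-cell stage ended it as well.

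The lists of other organs did not pass at this step. Among liver genes, 12 of 36 measured genes rose, 8 fell and 16 did not pass (12 and 8 adjusted over the list alone), with camera adjusted p = 0.761. Among genes of lung, gut, pancreas and kidney, 4 of 35 measured genes rose, 2 fell and 29 did not pass (2 and 1 adjusted over the list alone), with camera adjusted p = 0.882. Among cartilage and bone genes, 6 of 34 measured genes rose, 5 fell and 23 did not pass (6 and 5 adjusted over the list alone), with camera adjusted p = 0.833. Among epidermis genes, 2 of 37 measured genes rose, 9 fell and 26 did not pass (2 and 9 adjusted over the list alone), with camera adjusted p = 0.199. Among skeletal muscle genes, 14 of 37 measured genes rose, 4 fell and 19 did not pass (14 and 4 adjusted over the list alone), with camera adjusted p = 0.0871.

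Metabolic and housekeeping lists divided. In glycolysis 17 of 20 measured genes rose, 0 fell and 3 did not pass (17 and 0 adjusted over the list alone), with camera adjusted p = 3.13e-09, adjusted p = 0.0534 with an estimated correlation. In oxidative phosphorylation, which fell, 11 of 74 measured genes rose, 42 fell and 21 did not pass (11 and 42 adjusted over the list alone), with camera adjusted p = 4.31e-05, adjusted p = 0.416 with an estimated correlation. For the proteasome 6 of 30 measured genes rose, 18 fell and 6 did not pass (6 and 18 adjusted over the list alone), with camera adjusted p = 0.00528, adjusted p = 0.357 with an estimated correlation. Among cytosolic ribosomal protein genes, 9 of 62 measured genes rose, 31 fell and 22 did not pass (9 and 33 adjusted over the list alone), with camera adjusted p = 0.0186, adjusted p = 0.856 with an estimated correlation. Among ribosome biogenesis genes, 3 of 41 measured genes rose, 24 fell and 14 did not pass (3 and 24 adjusted over the list alone), with camera adjusted p = 0.00113, adjusted p = 0.0522 with an estimated correlation. Cell cycle genes rose: 26 of 44 measured genes rose, 10 fell and 8 did not pass (27 and 11 adjusted over the list alone), with camera adjusted p = 0.00596, adjusted p = 0.338 with an estimated correlation, and 0.0521 with a filter on dim genes (range 0.00191 to 0.0521). Among DNA methylation and chromatin regulators, 21 of 35 measured genes rose, 5 fell and 9 did not pass (21 and 5 adjusted over the list alone), with camera adjusted p = 0.00504.

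No list of markers of other cells passed. Among cumulus and granulosa cell markers, 4 of 21 measured genes rose, 3 fell and 14 did not pass (4 and 3 adjusted over the list alone), with camera adjusted p = 0.999. Vcan, a matrix proteoglycan that embryonic tissues also make, rose by 7.52 ± 0.24 and the steroid enzyme gene Hsd3b1 fell by 4.62 ± 0.28 (SE). Among sperm markers, 0 of 12 measured genes rose, 5 fell and 7 did not pass (0 and 5 adjusted over the list alone), with camera adjusted p = 0.317. Ldhc fell by 1.38 ± 0.42 (SE, adjusted p = 0.0130; 0.0787 without morula replicate 1 and 0.0777 after centring on the receptors, range 0.00107 to 0.0787). Spata18 fell by 1.30 ± 0.40 (SE, adjusted p = 0.0134; 0.0752 without morula replicate 1, 0.0554 without E10.5 replicate 1 and 0.107 after centring, range 0.00231 to 0.107). Ldhc and Spata18 lay within the receptor range at both stages. Among placenta and decidua markers, 1 of 21 measured genes rose, 5 fell and 15 did not pass (1 and 4 adjusted over the list alone), with camera adjusted p = 0.445. Peg10, which the imprinted list also holds, rose by 7.66 ± 0.25 and Syna fell by 2.24 ± 0.29 (SE), into the receptor range. Among leukocyte markers, 2 of 28 measured genes rose, 7 fell and 19 did not pass (2 and 7 adjusted over the list alone), with camera adjusted p = 0.855. None of the sex chromosome markers passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.888): Ddx3y lay at 9.35 and 6.71 (adjusted p = 0.186; 0.0129 without E10.5 replicate 3 and 0.00750 with the replicate number as a block, range 0.00750 to 0.477) and Eif2s3y at 3.84 and 5.17 (adjusted p = 0.627). E10.5 replicate 3 was the only E10.5 embryo with high Ddx3y signal (10.48).

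Between the morula and E10.5, 10973 genes changed, 5335 upward and 5638 downward. Rises of over 5 log2 units numbered 351 and falls of that size 335. Of the 33 lists 20 passed, 12 upward and 8 downward, and 9 did with an estimated correlation. Among genes named from lists, the lower of the 2 stages lay within the receptor range for Dppa2, Aqp9, Cldn7, Hoxd11, Hoxb9, Hoxa2, Prrx1, Prrx2, Dll1, Dbx1, Nppa, Myl2, Tnnt2, Peg3, Grb10 and Phlda2. The column names give 1 date for the 3 early stages and another for E10.5 and E16.5, and pools are compared with single embryos, so the stage, the date and the pooling cannot be told apart here. Among the receptor genes, which measure background, 6 rose and 283 fell (median -0.42), and after centring arrays on them 7033 genes rose and 3390 fell (4579 up and 7045 down centred on the upper quartile).

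From E10.5 to E16.5, genes of differentiated tissues rose, and genes of the cell cycle, of patterning and of the embryonic globins fell. Ahsg, the liver plasma protein fetuin-A, rose from 4.46 ± 0.17 to 18.11 ± 0.14 (SD, n = 3 each). The mean signal of the liver list went from 5.99 ± 0.033 to 12.96 ± 0.19 and that of the skeletal muscle list from 6.36 ± 0.036 to 12.16 ± 0.29 (SD, n = 3 each). Of the cell cycle genes 43 of 44 fell. Hbb-bh1, an embryonic globin gene, fell from 18.17 ± 0.11 to 4.47 ± 0.39 (SD, n = 3 each).

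The largest rises were those of Ahsg (chromosome 16, 22892015 to 22899451), Krt1 (chromosome 15, 101845426 to 101850786), Myh8 (chromosome 11, 67277124 to 67308634), Hrnr (chromosome 3, 93319749 to 93333572) and Amy2a5 (chromosome 3, 113249176 to 113258837). Ahsg rose by 13.65 ± 0.26 (SE, adjusted p = 7.31e-14). Krt1, a keratin of the suprabasal epidermis, rose by 12.78 ± 0.30, Myh8, the perinatal myosin heavy chain, rose by 12.67 ± 0.35, Hrnr, which encodes hornerin of the cornifying epidermis, rose by 12.54 ± 0.35, and Amy2a5, a pancreatic amylase gene, rose by 12.52 ± 0.42 (SE, adjusted p at most 6.04e-12). All 5 started within the receptor range. Among the falls, Hbb-bh1 (chromosome 7, 103841636 to 103843164) fell by 13.70 ± 0.28, Hba-x (chromosome 11, 32276400 to 32278116) fell by 11.41 ± 0.27 and Hbb-y (chromosome 7, 103851745 to 103853240) fell by 10.57 ± 0.27 (SE, adjusted p at most 2.39e-13). Because Hbb-y started at the top of the scale, the size of its fall is not exact. Igdcc3 (chromosome 9, 65141154 to 65185872), an immunoglobulin superfamily gene, fell by 9.44 ± 0.24, and Crabp2 (chromosome 3, 87948666 to 87953376), a retinoic acid binding protein gene, fell by 6.57 ± 0.30 (SE, adjusted p at most 1.25e-10).

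Tissue lists rose. For liver 33 of 36 measured genes rose, 0 fell and 3 did not pass (35 and 0 adjusted over the list alone), with camera adjusted p = 9.12e-36, and the fibrinogen chain genes Fga and Fgg rose by 11.94 ± 0.27 and 11.89 ± 0.28 (SE). For skeletal muscle 36 of 37 measured genes rose, 0 fell and 1 did not pass (36 and 0 adjusted over the list alone), with camera adjusted p = 1.51e-31, and the fast troponin genes Tnni2 and Tnnt3 rose by 11.13 ± 0.24 and 10.97 ± 0.50 (SE, adjusted p at most 1.57e-10). For epidermis 34 of 37 measured genes rose, 0 fell and 3 did not pass (34 and 0 adjusted over the list alone), with camera adjusted p = 7.87e-25, and Krt10, the keratin partner of Krt1, rose by 10.66 ± 0.26 (SE, adjusted p = 1.41e-13). In cartilage and bone 22 of 34 measured genes rose, 2 fell and 10 did not pass (23 and 2 adjusted over the list alone), with camera adjusted p = 2.43e-10. Ibsp and Spp1, which encode matrix proteins of bone, rose by 11.12 ± 0.29 and 8.95 ± 0.24, and the collagenase gene Mmp13 rose by 7.07 ± 0.27 (SE), whereas Sox9, the transcription factor of early cartilage, fell by 3.45 ± 0.27 (SE, adjusted p = 6.56e-08). Among leukocyte markers, 25 of 28 measured genes rose, 0 fell and 3 did not pass (26 and 0 adjusted over the list alone), with camera adjusted p = 2.02e-17. The neutrophil granule gene Ngp rose by 10.38 ± 0.32, and S100a9 and S100a8 rose by 8.02 ± 0.36 and 7.06 ± 0.40 (SE). Among genes of lung, gut, pancreas and kidney, 21 of 35 measured genes rose, 2 fell and 12 did not pass (24 and 3 adjusted over the list alone), with camera adjusted p = 1.24e-10. Among interferon and antigen presentation genes, 9 of 17 measured genes rose, 0 fell and 8 did not pass (11 and 0 adjusted over the list alone), with camera adjusted p = 2.83e-05.

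Neuronal genes rose: 24 of 33 measured genes rose, 1 fell and 8 did not pass (25 and 2 adjusted over the list alone), with camera adjusted p = 1.23e-08, adjusted p = 0.128 with an estimated correlation. Neurod6, a cortical transcription factor gene, rose by 4.96 ± 0.36, the kinase gene Camk2b rose by 4.78 ± 0.23 and the synaptotagmin gene Syt4 rose by 4.06 ± 0.29 (SE), and the neurofilament gene Nefm fell by 2.78 ± 0.28 (SE, adjusted p = 1.13e-06). Glia and Schwann cell genes did not pass in any comparison, and here 5 of 16 measured genes rose, 0 fell and 11 did not pass (5 and 0 adjusted over the list alone), with camera adjusted p = 0.121. Of the erythroid genes 16 of 24 measured genes rose, 3 fell and 5 did not pass (16 and 3 adjusted over the list alone), with camera adjusted p = 0.00353, adjusted p = 0.215 with an estimated correlation. The haemoglobin chaperone gene Ahsp rose by 4.53 ± 0.34 and the ferrochelatase gene Fech rose by 2.77 ± 0.40 (SE), against the 3 embryonic globins that fell, so that the mean of the list was -0.13 while its median was 1.43 and its test pointed upward. Among heart muscle genes, 11 of 22 measured genes rose, 5 fell and 6 did not pass (11 and 5 adjusted over the list alone), with camera adjusted p = 0.00839, adjusted p = 0.0941 with an estimated correlation. For oxidative phosphorylation 56 of 74 measured genes rose, 0 fell and 18 did not pass (63 and 0 adjusted over the list alone), with camera adjusted p = 1.01e-14, adjusted p = 0.105 with an estimated correlation.

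Smaller changes of lists depended on settings. Among primitive endoderm genes, 10 of 19 measured genes rose, 2 fell and 7 did not pass (12 and 3 adjusted over the list alone), with camera adjusted p = 0.0125, adjusted p = 0.145 with an estimated correlation. This list shares Hnf4a with the liver list and Pdgfra with the glia and Schwann cell list. Its rises at this step and the one before therefore do not show primitive endoderm cells. For endothelium 6 of 19 measured genes rose, 0 fell and 13 did not pass (6 and 0 adjusted over the list alone), with camera adjusted p = 0.0120, adjusted p = 0.413 with an estimated correlation, and 0.0509 with cyclic loess (range 0.00176 to 0.0509). In the list of trophectoderm and epithelium 17 of 34 measured genes rose, 9 fell and 8 did not pass (17 and 10 adjusted over the list alone), with camera adjusted p = 0.0346, adjusted p = 0.279 with an estimated correlation. That call was lost without E16.5 replicate 1 (adjusted p = 0.0792), with the upper quartile (0.0612) and with a filter on dim genes (0.0897, range 0.0168 to 0.0897).

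Lists of dividing and patterning cells fell. Of the cell cycle genes 0 of 44 measured genes rose, 43 fell and 1 did not pass (0 and 43 adjusted over the list alone), with camera adjusted p = 1.98e-23. Cdc20, an activator of the anaphase-promoting complex, fell by 3.94 ± 0.34, the mitotic kinase gene Plk1 fell by 3.85 ± 0.22 and Gins1 fell by 3.64 ± 0.25 (SE, adjusted p at most 2.77e-07). Of the Hox genes 0 of 34 measured genes rose, 23 fell and 11 did not pass (0 and 24 adjusted over the list alone), with camera adjusted p = 1.65e-09, and Hoxb9, Hoxd11 and Hoxd10 fell by 4.30 ± 0.24, 3.70 ± 0.34 and 3.39 ± 0.27 (SE) into the receptor range. In somite and limb bud patterning 1 of 36 measured genes rose, 23 fell and 12 did not pass (1 and 24 adjusted over the list alone), with camera adjusted p = 2.12e-07. Among neural progenitor genes, 1 of 21 measured genes rose, 15 fell and 5 did not pass (1 and 15 adjusted over the list alone), with camera adjusted p = 7.46e-07. Among DNA methylation and chromatin regulators, 0 of 35 measured genes rose, 33 fell and 2 did not pass (0 and 33 adjusted over the list alone), with camera adjusted p = 3.09e-14. Among ribosome biogenesis genes, 0 of 41 measured genes rose, 36 fell and 5 did not pass (0 and 38 adjusted over the list alone), with camera adjusted p = 3.62e-14. For the proteasome 0 of 30 measured genes rose, 20 fell and 10 did not pass (0 and 22 adjusted over the list alone), with camera adjusted p = 1.07e-05, adjusted p = 0.136 with an estimated correlation, and 0.0614 with cyclic loess (range 2.25e-06 to 0.0614). Among cytosolic ribosomal proteins, 2 of 62 measured genes rose, 0 fell and 60 did not pass (0 and 0 adjusted over the list alone), with camera adjusted p = 0.885, and 3.75e-04 with cyclic loess (range 3.75e-04 to 0.999).

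Among cumulus and granulosa cell markers, 3 of 21 measured genes rose, 1 fell and 17 did not pass (3 and 1 adjusted over the list alone), with camera adjusted p = 0.317, and Hsd3b1 rose by 5.55 ± 0.25 and the growth factor gene Btc rose by 1.72 ± 0.25 (SE). Among sperm markers, 2 of 12 measured genes rose, 0 fell and 10 did not pass (2 and 0 adjusted over the list alone), with camera adjusted p = 0.802, and Spata18 rose by 1.86 ± 0.36 (SE, adjusted p = 6.62e-04). Smcp rose by 0.96 ± 0.28 (SE, adjusted p = 0.0130), which was lost without E10.5 replicate 3 (adjusted p = 0.0648) and without E16.5 replicate 2 (0.0582, range 0.00404 to 0.0648). Among placenta and decidua markers, 0 of 21 measured genes rose, 4 fell and 17 did not pass (0 and 4 adjusted over the list alone), with camera adjusted p = 0.263 and 0.0371 with cyclic loess (range 0.0371 to 0.435), and Hand1 and Peg10, which other lists also hold, fell by 3.32 ± 0.28 and 3.07 ± 0.23 (SE). No sex chromosome marker passed (0 and 0 adjusted over the list alone, camera adjusted p = 0.512). As a list they passed without E10.5 replicate 3 (adjusted p = 0.0447, range 0.0447 to 0.794). Eif2s3y lay at 5.17 and 7.84 (adjusted p = 0.309) and Ddx3y at 6.71 and 9.13 (adjusted p = 0.217). Without E10.5 replicate 3 they passed at 0.0221 and 0.0144, and without E16.5 replicate 2 at 0.0186 and 0.0139 (ranges 0.0186 to 0.715 and 0.0139 to 0.581). E10.5 replicate 3 alone of its stage had high Eif2s3y signal (10.18), and E16.5 replicate 2 alone of its stage had low signal (2.67). Passes without either array therefore follow which embryos carried Y-linked signal and cannot be read as a change with stage.

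Between E10.5 and E16.5, 7987 genes changed, 3700 upward and 4287 downward. Rises of over 5 log2 units numbered 292 and falls of that size 12. Of the 33 lists 21 passed, 14 upward and 7 downward, and 13 did with an estimated correlation. Of the genes named from lists, Hoxb9, Hoxd11, Hoxd10, Neurod6, Syt4, Ngp, S100a9, S100a8, Tnni2, Tnnt3, Ibsp, Spp1, Mmp13, Fga, Fgg, Btc, Spata18, Smcp and Hand1 lay within the receptor range at their lower stage. The 6 arrays of the late date fitted alone gave 8516 changed genes, 7897 of them shared. Rises outnumbered falls with cyclic loess (4162 up and 3576 down), centred on the receptors (3886 up and 3363 down) and centred on the upper quartile (4136 up and 3571 down). With quantile normalization applied again, falls outnumbered rises (3443 up and 4614 down). Over all comparisons, the median, mean and test of a called list differed in sign for the erythroid genes at E16.5 only, and for 21 of the 77 list results that did not pass.

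**Figure D3:**
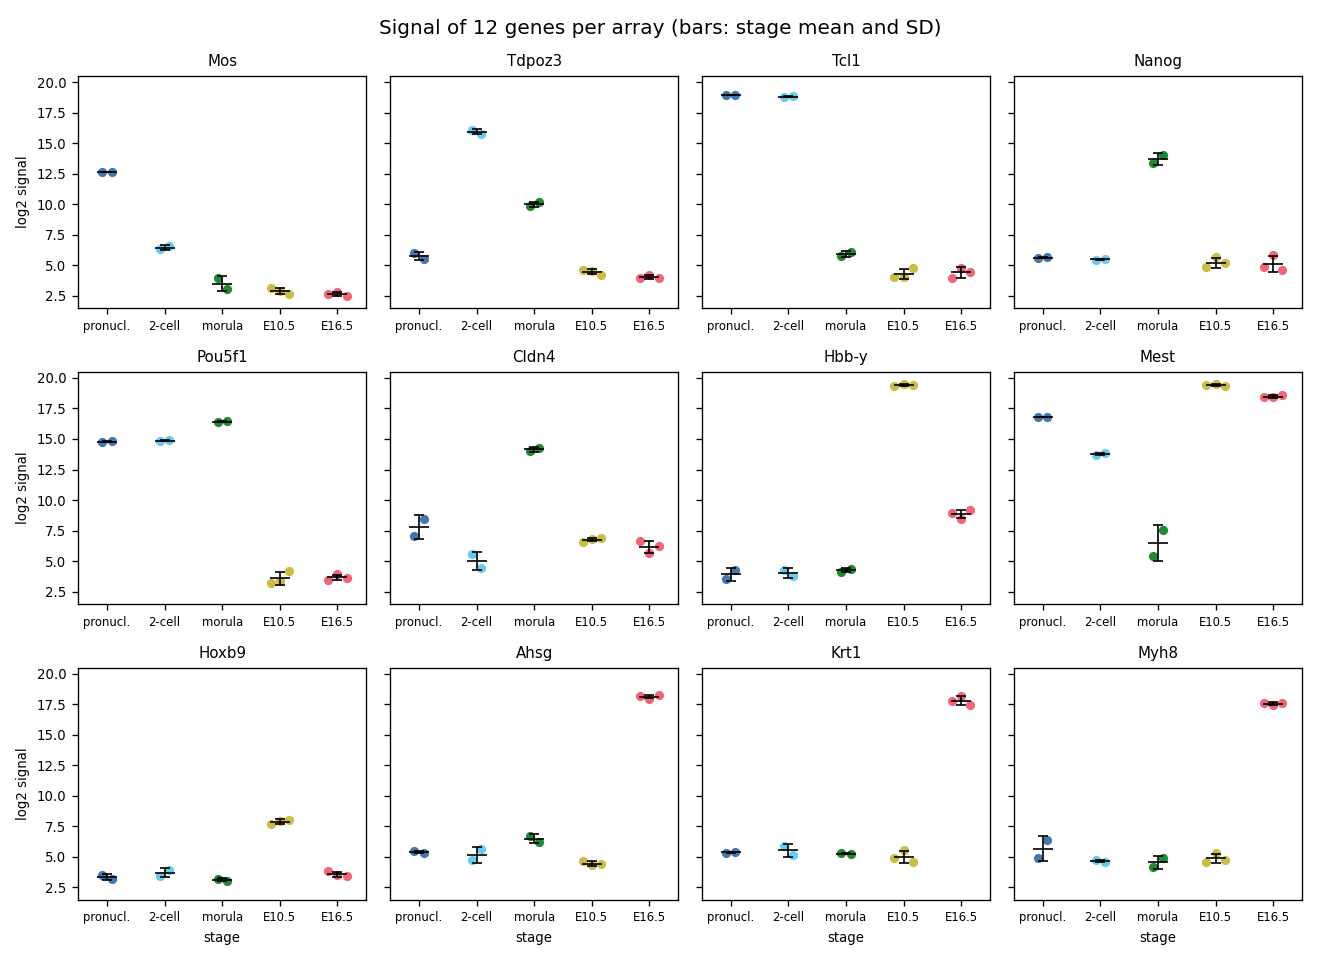
Log2 signal (vertical axes) of 12 genes on each array (points) at the 5 stages (horizontal axes, pronucl. for pronuclear), with bars for the stage mean and SD (n = 2 or 3 arrays). Tdpoz3 is highest at the 2-cell stage (15.93), Nanog and Cldn4 at the morula stage (13.71 and 14.14), Hbb-y at E10.5 (19.41) and Ahsg at E16.5 (18.11).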

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

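The added host gene probe sets and the fits of 1 date only were tests chosen after the data had been seen. The counts of changed genes, of genes past the F test and of genes highest at the 2-cell stage stayed within 1.5 times their values in every alternative run. Leaving out 1 array gave 5935 to 8000 genes for 2-cell versus pronuclear, 7403 to 8931 for morula versus 2-cell, 9390 to 11418 for E10.5 versus morula and 6807 to 8204 for E16.5 versus E10.5, 16131 to 16966 for the F test and 1063 to 1393 for the 2-cell peak. A lone remaining array of a stage was assumed there to vary like the other stages. The numbers of called lists moved by more only with an estimated correlation, to 3, 4, 9 and 13 in order of development, because that correlation widens the spread of a list's mean. Of 1960 values of named genes over the alternatives 1941 kept direction and call, 6 lost the call, 13 gained one and 0 turned, and with arrays left out 15 of 2004 lost and 7 gained it. Of 1551 list values 37 lost and 3 gained the call and 0 turned, and with arrays left out 9 of 1584 lost and 1 gained it. None of the 55 called list medians turned under the 4 scalings. The median change of all genes was -0.028, 0.11, -0.16 and -0.080 as deposited, -0.20, 0.031, 0.32 and 0.036 centred on the receptors, and 0.14, 0.34, -0.41 and 0.055 centred on the upper quartile, so the sharing between rises and falls is relative to the scaling. The replicate number as a block gave 7179, 8150, 10199 and 7655 changed genes. Over 21 pairs of arrays with the same number, deviations from the stage mean correlated between -0.110 and 0.0458 across genes. Of 12 arrays, 2 correlated best with their own number. In a stage of 2 arrays the deviations mirror each other, so values among the early stages repeat for both numbers. These values show no strong pairing by number and do not exclude a weak one.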

Other observations

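The families of related symbols, the tests of sex and of Tmsb4x and Vim, and the selection of the patterns weighed here were chosen after the results had been seen. Gene families by symbol stem, 340 of them with at least 8 members, gave 163 calls in 1360 camera tests, and none passed with an estimated correlation (lowest adjusted p = 0.232). Whether probes tell related members of a family apart was not tested, so counts within a family may not be counts of separately measured genes. Histone genes (Hist) rose in 30 of 59 from the pronuclear to the 2-cell stage (camera adjusted p = 1.27e-05, adjusted p = 0.706 with an estimated correlation, 19 to 38 under the other scalings). They rose in 38 of 59 from the morula to E10.5 (36 to 46 under the other scalings) and fell in 41 of 59 from E10.5 to E16.5 (17 to 43 under the other scalings). Of the F-box genes named Fbxw, 18 of 24 fell at the first step and 17 of 24 at the second (camera adjusted p = 1.37e-07, adjusted p = 0.232 with an estimated correlation). Magea and Rhox genes, clustered on the X chromosome and known from germ cells and early embryos, rose to the morula in 6 of 8 and 14 of 30 (Rhox 11 to 17 under the other scalings) and fell to E10.5 in 7 of 8 and 18 of 30 (Rhox 12 to 21 under the other scalings), and Xlr genes fell to E10.5 in 10 of 10 (camera adjusted p = 3.44e-06, adjusted p = 0.349 with an estimated correlation).

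Genes of intraflagellar transport (Ift), which builds cilia, rose from the morula to E10.5 in 14 of 14 (camera adjusted p = 1.06e-04, adjusted p = 0.278 with an estimated correlation), and the Wnt receptor genes named Fzd in 8 of 10 (camera adjusted p = 8.73e-04, adjusted p = 0.232 with an estimated correlation). From E10.5 to E16.5, nucleoporin genes (Nup) fell in 19 of 19 (camera adjusted p = 3.72e-08, adjusted p = 0.232 with an estimated correlation), splicing factor genes (Srsf) fell in 9 of 11 and zinc finger genes (Zfp) fell in 167 of 355 (114 to 178 under the other scalings). Annexin genes (Anxa) rose in 11 of 12 (camera adjusted p = 3.45e-08, adjusted p = 0.232 with an estimated correlation) and galectin genes (Lgals) in 8 of 8 (camera adjusted p = 7.67e-07, adjusted p = 0.232 with an estimated correlation). The median of none of these families turned under the 4 scalings.

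Y-linked genes, none of which passed the test over all 12 arrays, differed in signal between arrays. Uty lay at 3.52 and 3.57 in the pronuclear pools and at 7.61 and 8.07 in the 2-cell pools, and Ddx3y at 6.75 and 5.50 in 2-cell pools and 8.87 and 9.84 in morulae. Eif2s3y stayed within the receptor range in all early pools (2.63 to 4.08), and Kdm5d lay between 2.51 and 6.17, within the range or at its upper end. Onset stages were not compared by a test. At the late stages Eif2s3y lay at 10.18 in E10.5 individual 3 and at 10.62 and 10.24 in E16.5 individuals 1 and 3, against 2.99 and 2.32 in the other 2 E10.5 embryos and 2.67 in E16.5 individual 2. These differences within a stage enter the spread that all stages share in the fit. They widen it for Y-linked genes in the early comparisons too.

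E16.5 individual 2 lay apart from the other 2 embryos of its stage: the standard deviation of its residuals over genes was 1.34 times the larger of the others. A smaller signal range of its array as the whole cause is argued against by cyclic loess, after which the ratio was still 1.29. Cyclic loess removes only shifts that follow the signal level, so a noisier array would keep a high ratio and is not excluded. The receptor median of this array was 4.16, against 3.75 and 3.76 on the other 2 arrays. A difference of sex beyond the Y-linked genes was tested across 21028 genes off the Y chromosome. The deviation of E16.5 individual 2 correlated at -0.00275 with the difference between E10.5 embryos without and with Y-linked signal. That difference comes from another stage and rests on 2 embryos against 1. A few genes that differ by sex would also hardly move a correlation over so many genes, so the test does not decide whether sex contributes. For 7 exocrine pancreas genes of the fixed lists the signal of E16.5 individual 2 was lower than in both other embryos, by a median of -1.69 after cyclic loess (Clps 13.37 against 15.70 and 15.87), so less pancreas RNA may account for those genes. Other lists differed too after cyclic loess, by medians of 0.69 for epidermis, 0.56 for erythroid cells, 0.39 for cartilage and bone, -0.55 for endothelium, -0.46 for neural progenitors and -0.45 for neurons, which pancreas RNA does not explain. Slower development, loss of tissue at collection and the quality of this embryo's RNA or array were not tested and stay open.

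The receptor genes fell from the morula to E10.5 (6 rose, 283 fell, median -0.42), although neither stage is known to use them. An array-wide background difference may account for this: keratin-associated protein and beta-defensin genes (Krtap and Defb, 92 genes), which played no part in choosing the receptors, changed by a median of -0.34, 0.0797 log2 units from that of the receptors, with 1 that rose and 22 that fell. Their medians also matched those of the receptors between stages of 1 date (0.18 and 0.17 for 2-cell versus pronuclear, 0.109 and 0.110 for morula versus 2-cell, -0.14 and -0.13 for E16.5 versus E10.5). The match therefore does not point to the dates as the source. An earlier test, a count of receptor changes after centring on the receptors themselves, was dropped because the centring fixes its outcome. The date is shared by all arrays of each stage, so a difference of background by stage, input or pooling stays open.

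Cumulus and granulosa cell markers fell from the 2-cell stage to the morula as a list (camera adjusted p = 0.0127, adjusted p = 0.0738 with an estimated correlation), with 7 of 21 that fell, and cumulus cells carried along with the early pools are a candidate explanation. Of 7 abundant cumulus genes, 4 (Tnfaip6, Inha, Cyp11a1 and Vcan) lay above the receptor range at the 2-cell stage, the number set beforehand for carried-along cells, and 3 of 6 transcripts abundant in somatic cells (Lgals1, S100a6 and Sparc) lay above it and fell, between the bounds set beforehand. Of the 4, Inha did not pass from the 2-cell stage to the morula (7.38 and 7.23, adjusted p = 0.770). Against carried-along cells, Tmsb4x and Vim, which are abundant in somatic cells and reach 17.83 and 15.75 at E10.5, lay at 5.96 and 5.92 in 2-cell pools, the higher at -0.54 relative to the upper end of the receptor range (6.40 without the receptors that rose there). Cyp11a1 and Hsd3b1 rose from 13.47 to 15.36 and from 13.48 to 15.13 before they fell, while Inha fell from 11.03 to 7.38. These values argue against cumulus cells as the source of Cyp11a1 and Hsd3b1, but 2 transcripts near background do not exclude a small share for the others that fell, and 9 of the 21 markers lay above the range at E10.5 too.

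For E16.5 versus E10.5, the 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05. The real one gave 7987 genes, 1 of the 10 splits, the real one itself, reached that number, and the highest other gave 4. Every other split mixes both stages in each group, so the stage difference enters the spread and few calls are bound to result. No conclusion is drawn from these counts.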
